A study of Mus musculus with 8 samples.

How the data were processed

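RNA was measured in CD4+ T cells sorted from enzymatically digested knee joints of male mice aged 16 weeks with antigen-induced arthritis, a joint inflammation started by an antigen to which the animal has been immunised. 4 libraries came from wild-type cells and 4 from Slc7a5 knockout cells, per the labels. Total RNA was extracted with a column kit for small amounts, amplified and made into libraries with a low-input kit, and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. Such amplification can lose scarce transcripts at random when few cells are used, and the number of cells per library was not given in the sources used here. The labels do not say that each library came from its own animal, so the p-values measure the spread between these libraries, which may be technical in part.

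The deposited file holds raw counts, whole numbers of reads per gene symbol, not normalized by the authors, for 24421 symbols. HISAT2 2.1.0, featureCounts, edgeR 3.28.1 and the mm10 build are named, per the submitters' processing notes. The gene annotation, the strand setting and the handling of duplicate reads were not given in the sources used here. Without a known strand setting, reads of overlapping genes and of antisense partners cannot be told apart. None of the 13 mitochondrially encoded protein genes was among the symbols used here, so their share could not serve as a sign of RNA quality. The mm10 build carries the coordinates of GRCm38, and positions were taken from a RefSeq gene table of GRCm38.p6 in which 23204 symbols (95.0%) were found.

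Everything that follows was computed from those counts in R 4.3.3. Low counts were removed with the filterByExpr function of edgeR 4.0.16 (minimum count 10, minimum total 15), libraries were scaled by TMM, and knockout was compared with wild type by edgeR's quasi-likelihood test with robust dispersion, with genotype as the only term and Benjamini-Hochberg adjustment. A gene passed at an adjusted p under 0.05. A positive log2 fold change means higher in knockout, and its standard error (SE) is the log2 fold change over the square root of the F statistic. CPM values are counts scaled to the effective library size after TMM, given as mean ± SD. The filter removed Slc7a5, whose test therefore comes from the same fit without a filter. Single values per library were compared by two-sided exact permutation tests, whose smallest possible p with 4 against 4 libraries is 0.0286. A gene at 0 in all libraries of a genotype is given as a lower bound of the fold, computed against 3 counts over the pooled libraries of that genotype; this floor covers counting error only.

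The sample groups, the tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule named Slc7a5, then the 12 higher and 12 lower genes with the smallest p among those that passed, or, if fewer than 10 passed, the 5 higher and 5 lower genes with the smallest p and a mean CPM of at least 5, leaving out predicted gene models; up to 4 passing members of each list; and 10 fixed genes, of which 1 is not reported here and the others are Slc3a2, Cd4, Cd3e, Foxp3, Tbx21, Gata3, Il17a, Ifng and Myc. The lists comprised 22 gene lists and 16 lists of markers of T cells, of other cell types and of RNA quality. A list with at least 3 tested members was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the correlation between genes preset at 0.01, adjusted over the 27 lists tested. Members were also adjusted over each list alone, and the median of a list was placed among 10000 random lists matched on mean expression.

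The alternatives were no filter, a stricter filter, 3 other scalings, DESeq2 1.42.0, limma voom with and without library quality weights, the replicate number as a block, each library left out, a fold threshold, a looser threshold, an estimated correlation in camera, and fry. Added after the data were seen were a minimum mean CPM of 50, an offset for GC content, both together, and the removal of the libraries with the fewest genes. The GC offset was a smooth curve per library (loess, span 0.75) of the log2 CPM deviation against transcript GC content, fitted on genes with a mean log2 CPM above 5. GC content came from GENCODE mouse transcripts of GRCm38 and was known for 8200 tested genes (96.6%).

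The scripts were tested on simulated data: counts for the 8489 tested genes were drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. At a dispersion of 0.1, edgeR recovered 40.0% of the 2-fold and 100% of the 4-fold changes with 8 false calls. At the dispersions fitted to each gene here it recovered 0% of both, and DESeq2 recovered 1.00% and 17.0% with 144 false calls. At the dispersion of the abundant genes edgeR recovered 15.0% and 93.0%. A simulated list of 20 genes lowered 2-fold had a camera adjusted p of 6.07e-23 at a dispersion of 0.1 and 0.613 at the fitted dispersions. None of 20 random lists was called (0 in both). The simulated genes were drawn independently, so these lists cannot show how often correlation between genes leads camera to a false call.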

Results

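CD4+ T cells from arthritic mouse knees were compared between 4 wild-type and 4 Slc7a5 knockout libraries. The comparison asks how loss of this amino acid transporter alters the transcripts of T cells at the site of inflammation. The wild-type libraries held 36436923, 26927245, 31353864 and 21873678 counts in replicates 1 to 4, and the knockout libraries 22878362, 21689444, 25853856 and 18837650. Of 24421 symbols, 12849 had at least 1 count in some library and 8489 were tested. Genes with at least 1 count numbered 10139, 9934, 9815 and 7957 in the wild-type libraries and 8640, 7684, 9358 and 5221 in the knockout libraries (9461 ± 1012 against 7726 ± 1805, exact permutation p = 0.143, n = 4 each). Only 3786 tested genes (44.6%) were seen in all 8 libraries. Spearman correlations of log2 CPM across genes ran from 0.708 to 0.826 within wild type, from 0.489 to 0.713 within knockout. They ran from 0.494 to 0.790 between genotypes. Knockout replicate 4 stood apart, at 0.489 to 0.544 with the other libraries.

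Slc7a5, the light chain of the LAT1 transporter of large neutral amino acids, lies on chromosome 8 from 121881146 to 121907686 (GRCm38). It had 385, 194, 410 and 0 counts in wild-type replicates 1 to 4 and 0 counts in each of the 4 knockout libraries. Against a floor of 3 counts over the knockout libraries together, which covers counting error only, it was at least 252-fold lower. It was detected in 3 of 4 wild-type and 0 of 4 knockout libraries (Fisher's exact test, two-sided p = 0.143). The wild-type CPM was 7.58 ± 5.57, and the exact permutation p was 0.143 (n = 4 each). In edgeR's quasi-likelihood test without a filter the adjusted p (Benjamini-Hochberg) was 0.365, while DESeq2 gave an adjusted p of 0.0183. Of the 1407 genes within 1.5 times the wild-type mean of Slc7a5, 191 (13.6%) were likewise at 0 in every knockout library. The labels do not give the deleted part of the gene, so the zeros cannot be set against it and do not by themselves check the labels. Wild-type replicate 4, at 0, is not checked by this gene either. Slc3a2, the heavy chain that pairs with Slc7a5, was at 296 ± 56.8 CPM in wild type and 416 ± 39.4 CPM in knockout, and 4 of 4 knockout libraries lay above all wild-type libraries. It did not pass (log2 fold change 0.49, SE 0.25, edgeR adjusted p = 0.9999).

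**Figure D1:**
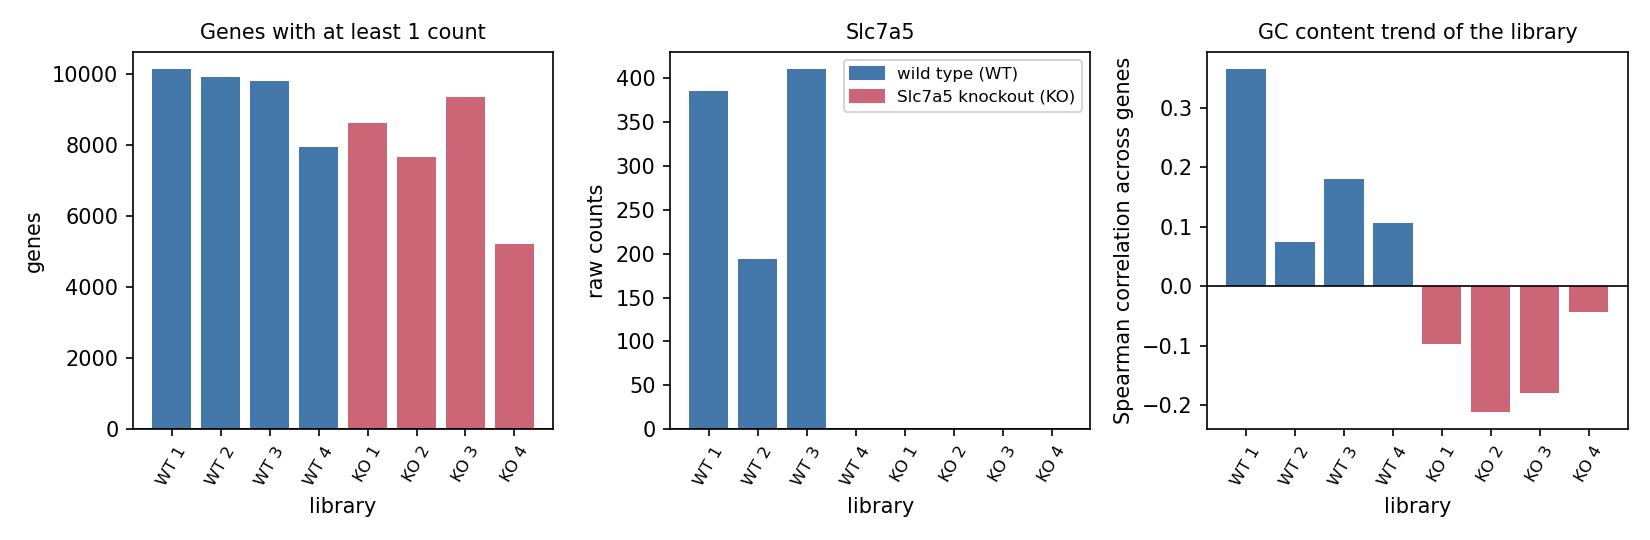
Bars show, for each wild-type (WT) and knockout (KO) library, the number of genes with at least 1 count, the raw counts of Slc7a5, and the Spearman correlation across genes between transcript GC content and the library's deviation in log2 CPM from the mean of all libraries. Slc7a5 counts appear in 3 wild-type libraries, and the correlation is above 0 in the 4 wild-type and below 0 in the 4 knockout libraries.

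The 5 lower and 5 higher genes with the smallest p were Ltb, Zgpat, Nkg7, Pkm and Tnfaip3, with lower estimates in knockout, and Skil, Ddx3y, Bclaf1, Clk1 and Yme1l1, with higher ones. Ltb, the membrane-bound lymphotoxin beta, was at 2145 ± 164 CPM in wild type and 1150 ± 33.8 CPM in knockout (log2 fold change −0.90, SE 0.16, n = 4 each). Skil, a repressor of TGF-beta signalling through SMAD proteins, was at 704 ± 44.7 and 1468 ± 144 CPM (log2 fold change 1.06, SE 0.18). For every gene of these 10, each knockout library lay beyond all 4 wild-type libraries. The genes were picked by their p on these same libraries, so that separation is no further support. None passed the test, however. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes were called (smallest adjusted p = 0.437). At an unadjusted p under 0.05 there were 326 genes (159 higher, 167 lower), where evenly spread p-values would give 424. DESeq2 called 387 of 10659 genes (61 higher, 326 lower), 118 of them among the 8489 genes tested in edgeR, limma voom 4 and limma voom with quality weights 4. Of the DESeq2 calls, 358 (92.5%) were at 0 in at least 1 library and 196 at 0 in every knockout library. Zeros were common among all genes too, since 3803 of the 12849 genes with a count were seen in every library.

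Skil was 1 of the 5 higher genes with the smallest p. Ddx3y, a Y-linked RNA helicase, was at 153 ± 24.6 CPM in wild type and 527 ± 253 CPM in knockout (log2 fold change 1.79, SE 0.36). Bclaf1, a nuclear factor of transcription and RNA processing, was at 126 ± 56.8 and 437 ± 72.2 CPM (1.80, SE 0.37). Clk1, a kinase of splicing factors, was at 313 ± 75.8 and 732 ± 174 CPM (1.22, SE 0.26). Yme1l1, a mitochondrial protease, was at 389 ± 61.8 and 902 ± 299 CPM (1.21, SE 0.27). Reads of Ddx3y may be shared with its X-linked copy Ddx3x, and Yme1l1 overlaps Mastl. Among the 5 lower genes, Pkm, the glycolytic pyruvate kinase, was at 2676 ± 328 and 1355 ± 332 CPM (log2 fold change −0.98, SE 0.21). Tnfaip3, the NF-kappaB inhibitor A20, was at 1004 ± 138 and 538 ± 49.8 CPM (−0.90, SE 0.19). Zgpat, a zinc finger repressor, had counts in all 4 wild-type libraries (66.9 ± 39.2 CPM) and 0 in all 4 knockout libraries. That is at least 1970-fold lower by the floor, which covers counting error only. Zgpat overlaps Arfrp1 and Zbtb46. With adjusted p-values of 0.437 to 0.460 in edgeR, none of these 10 genes passed. The 5 higher genes had transcript GC contents at or below the percentile 9.45 of abundant genes and Ltb at the percentile 99.8. With an offset for GC content, the log2 fold change was 0.67 for Skil, 1.18 for Ddx3y, 1.37 for Bclaf1, 0.80 for Clk1 and 0.69 for Yme1l1. It was −0.38 for Ltb, −0.68 for Pkm, −1.47 for Nkg7 and −0.94 for Tnfaip3.

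Genes of the Th1 and cytotoxic program, which marks interferon-gamma producing T cells, were lower in knockout as a group. Of 20 tested members 18 had lower and 2 higher estimates, and the median log2 fold change was −1.10, below all 10000 random lists matched on expression (percentile 0). Adjusted over the list alone, 3 members fell and 0 rose, while 0 passed over all genes tested in edgeR (5 at an unadjusted p under 0.05, all lower). One was Nkg7, a cytotoxic granule protein, at 1038 ± 276 and 347 ± 157 CPM (log2 fold change −1.58, SE 0.32). Another was Cxcr6, a chemokine receptor of tissue T cells, at 1637 ± 468 and 828 ± 254 CPM (−0.98, SE 0.29). The last was Gzmk, granzyme K, at 25.8 ± 12.8 CPM against 0 in all 4 knockout libraries. That is at least 746-fold lower by the floor, which covers counting error only and not the loss of a transcript from a library. The summed CPM of the list was 4886 ± 661 in wild type and 2557 ± 467 in knockout, and each knockout library lay below every wild-type library. The exact permutation p was 0.0286, the smallest possible (n = 4 each), and 0.217 after Benjamini-Hochberg adjustment over the 38 lists. The camera adjusted p was 0.00468, the only one of 27 lists to pass. The call was lost with an estimated correlation (adjusted p = 0.572), without wild-type replicate 4 (0.05003) and without knockout replicate 3 (0.142). Other lists lay low among matched random lists as well: T cell identity at the percentile 0.12, T cell receptor activation at 0.55, glycolysis at 0.84, immediate early and heat shock genes at 1.19 and migration and adhesion at 2.44. The T cell identity genes summed to 12020 ± 1749 and 9825 ± 1024 CPM (exact permutation p = 0.0571, adjusted 0.241, n = 4 each), while MHC class II transcripts were higher in 3 of 4 knockout libraries.

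Not all members took part. Gzmb, granzyme B, was at 480 ± 171 and 491 ± 249 CPM. Ifng, the cytokine interferon gamma, was at 161 ± 49.9 CPM in wild type and at 21.2, 0, 77.4 and 0 CPM in knockout replicates 1 to 4 (log2 fold change −2.70, SE 1.82). Tbx21, which encodes the Th1 regulator T-bet, was at 67.4 ± 52.6 and 6.79 ± 13.5 CPM (log2 fold change −3.31, SE 2.30). Neither passed (edgeR adjusted p = 0.9999 for both), and leaving out 1 knockout library moved both values by over 1.5 times. The log2 fold change of Tbx21 was −10.71 without knockout replicate 1, which left 2 counts in knockout, and −9.82 with the replicate block. That of Ifng was −4.50 without knockout replicate 3 and −6.99 with the block. Fasl, a death ligand, was at 297 ± 92.3 and 153 ± 69.0 CPM, and Cxcr3, a chemokine receptor of Th1 cells, at 183 ± 63.4 and 81.4 ± 25.3 CPM.

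**Figure D2:**
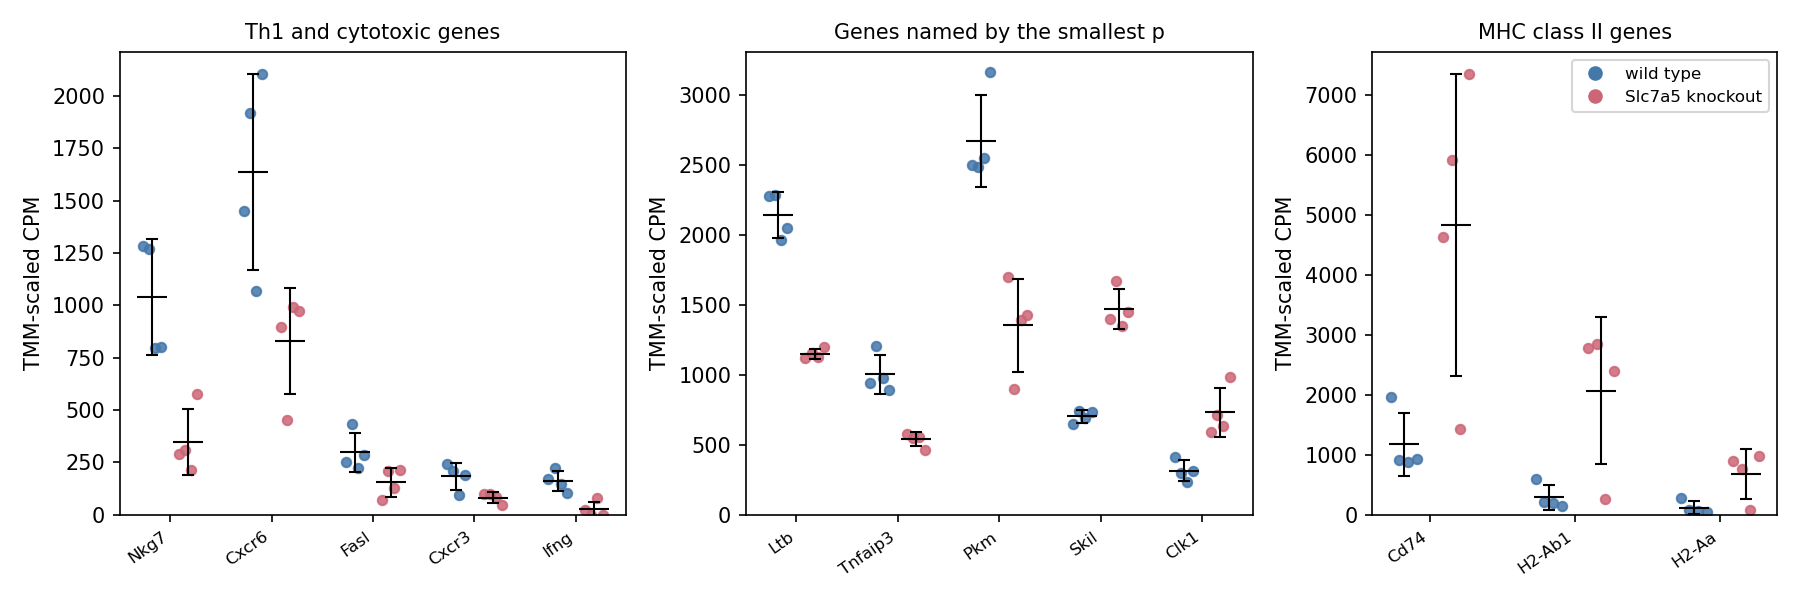
Points are TMM-scaled CPM values of single libraries, 4 wild type and 4 Slc7a5 knockout, for Th1 and cytotoxic genes, for genes named by the smallest p, and for MHC class II genes; black lines mark the mean and bars 1 SD, drawn only above 0. Nkg7 and Ltb lie lower and Skil higher in all 4 knockout libraries, whereas 1 knockout library stays near the wild-type level of Cd74.

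Lists of other helper lineages did not pass, and their difference from the Th1 and cytotoxic list was not tested. The Th17 list (18 tested, camera adjusted p = 0.843) summed to 3846 ± 2170 and 3955 ± 749 CPM, with 7035 CPM in wild-type replicate 4. The Th2 list (8 tested, median 0.03, adjusted p = 0.699) summed to 1709 ± 388 and 1712 ± 471 CPM. Il17a, the Th17 cytokine, was at 91.0 ± 82.8 and 39.8 ± 16.4 CPM (log2 fold change −1.19, SE 0.98). Gata3, the Th2 regulator, was at 1174 ± 301 and 1129 ± 348 CPM (−0.06, SE 0.27). The regulatory T cell list (21 tested, median −0.12, adjusted p = 0.620) included Foxp3, its master regulator, at 95.6 ± 45.1 and 69.8 ± 29.4 CPM (−0.45, SE 0.72). The naive and resting list (16 tested, 13 with higher estimates, median 0.29) had an adjusted p of 0.255, and the follicular helper and inhibitory receptor list (15 tested, median −0.04) 0.620. None of these genes passed in edgeR, where the adjusted p of each was 0.9999. The sign of the fold change of Gata3 turned without wild-type replicate 1 (0.10) and without knockout replicate 4 (0.10), and that of Il17a in limma voom with quality weights (0.11). Without wild-type replicate 4 the log2 fold change of Il17a was −0.44, and that of Foxp3 was −0.11 without wild-type replicate 1.

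Transcripts of T cell receptor activation were lower in part. In the T cell receptor activation list, 2 of 22 tested members fell when adjusted over the list alone, Tnfaip3 and Nr4a1. Over all genes tested in edgeR, 0 members passed and 5 were at an unadjusted p under 0.05 (4 lower, 1 higher). Nr4a1, an early response gene of receptor engagement, was at 3911 ± 985 and 1741 ± 742 CPM (log2 fold change −1.17, SE 0.29). The summed CPM of that list was 11980 ± 1942 and 7953 ± 1682 (exact permutation p = 0.0286, adjusted 0.217, n = 4 each). Camera, which sets a list against all other genes, gave an adjusted p of 0.696. Immediate early and heat shock genes, which tissue digestion raises, had lower estimates for 16 of 20 tested members (median −0.28) and 0 passed adjusted over the list alone. They summed to 15690 ± 1858 and 12520 ± 1766 CPM (exact permutation p = 0.0857, adjusted 0.326, n = 4 each), with a camera adjusted p of 0.878. In the T cell identity list, 13 of 15 tested members had lower estimates (median −0.39, camera adjusted p = 0.666) and 0 fell adjusted over the list alone. Cd3e, a receptor chain, was at 477 ± 66.2 and 365 ± 24.2 CPM (log2 fold change −0.39, SE 0.22). Cd4 was at 458 ± 94.2 CPM in wild type and at 427, 344, 402 and 1.78 CPM in knockout replicates 1 to 4, so the low mean of knockout rests on replicate 4 (log2 fold change −0.64, and −0.24 without it). That library held 34 Cd4 counts and a Cd3e level of 382 CPM. The cytokine list (22 tested, adjusted p = 0.590) had 1 member lower over the list alone, Ltb.

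Among metabolic lists, glycolysis had a lower summed CPM in knockout without passing the adjusted test. It was at 9057 ± 972 CPM in wild type and 5606 ± 876 CPM in knockout (exact permutation p = 0.0286, adjusted 0.217, n = 4 each), with 16 of 20 tested members at lower estimates and a median log2 fold change of −0.45. Pkm fell when adjusted over the list alone, and Aldoa, an aldolase, was at 2148 ± 324 and 1184 ± 475 CPM without passing. The camera adjusted p was 0.590. Pkm and Aldoa transcripts lay at the GC percentiles 93.8 and 91.3, and with the GC offset their log2 fold changes were −0.68 and −0.61. The aminoacyl-tRNA synthetase list, whose enzymes load amino acids onto tRNA, summed to 1941 ± 334 CPM in wild type and 2575 ± 262 CPM in knockout (exact permutation p = 0.0286, adjusted 0.217, n = 4 each). Its members went both ways, with 10 higher and 10 lower estimates of 20 tested, a median log2 fold change of 0.07 and a mean of −0.24. Its member Eprs was at 385 ± 70.4 and 742 ± 245 CPM without passing, and its camera adjusted p was 0.590. The camera adjusted p was 0.945 for amino acid transporters, 0.590 for ATF4 targets, 0.611 for sterol and fatty acid synthesis and 0.590 for oxidative phosphorylation. It was 0.590 for MYC targets and ribosome biogenesis, 0.590 for the cell cycle, 0.298 for endoplasmic reticulum stress and 0.699 for autophagy and the lysosome. Of the members of these 8 lists, 0 passed adjusted over the list alone. Myc, a growth regulator, was at 119 ± 46.1 and 143 ± 28.3 CPM (log2 fold change 0.26, SE 0.47, edgeR adjusted p = 0.9999; 0.02 without wild-type replicate 3). Migration and adhesion genes summed to 9002 ± 759 and 6977 ± 267 CPM (exact permutation p = 0.0286, adjusted 0.217, n = 4 each; camera adjusted p = 0.945). The lists of the interferon response and of apoptosis and p53 had camera adjusted p-values of 0.611 and 0.979.

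MHC class II transcripts, which antigen-presenting cells make, were higher in 3 of 4 knockout libraries. Cd74, the invariant chain, was at 1172 ± 532 CPM in wild type and at 4636, 5926, 1434 and 7352 CPM in knockout replicates 1 to 4 (log2 fold change 2.05, SE 0.46). H2-Ab1 was at 290 ± 210 CPM and at 2781, 2840, 262 and 2403 CPM (log2 fold change 2.84, SE 0.70). H2-Aa (log2 fold change 2.54, SE 0.82) and H2-Eb1 (2.21, SE 0.64) followed. These 4 members of the monocyte, macrophage and dendritic cell list rose when adjusted over the list alone and 0 passed over all genes tested in edgeR. The camera adjusted p of the list (13 tested, median 1.41) was 0.144, and it was 0.0294 without wild-type replicate 1 and 0.0316 without knockout replicate 1. Of the 13 tested members of that list, 9 had higher and 4 lower estimates. Members besides the 4 MHC class II genes did not pass adjusted over the list alone. Lyz2, at 23.7 ± 1.76 and 6.47 ± 12.7 CPM, was among the lower ones.

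Markers of the further cell types named here were scarce. The monocyte, macrophage and dendritic cell list, in contrast, summed to 2071 ± 905 CPM in wild type and 8349 ± 3957 CPM in knockout. The CD8 T and natural killer cell list summed to 229 ± 78.2 and 216 ± 109 CPM (camera adjusted p = 0.590), although 4 of its 6 tested members had higher estimates (median 1.35). The summed CPM was 89.0 ± 73.7 and 85.2 ± 86.5 for the neutrophil list (0.843), and 120 ± 29.9 and 153 ± 81.3 for the skeletal muscle list (0.590). Too few members were tested for camera in 10 further lists with symbols in the file. B and plasma cell markers, of which 11 of 14 were among the symbols, summed to 32.8 ± 22.5 and 43.6 ± 34.7 CPM. Gamma-delta T cell markers summed to 7.96 ± 13.5 and 4.09 ± 8.19 CPM. Only 3 of those 10 markers were among the symbols, so their low sum cannot show that such cells were absent. Osteoclast markers summed to 136 ± 31.7 and 135 ± 94.7 CPM, synovial fibroblast markers to 133 ± 27.3 and 81.8 ± 41.8 CPM, and chondrocyte and osteoblast markers to 91.5 ± 62.3 and 54.8 ± 46.1 CPM. Endothelial and mural markers summed to 108 ± 43.1 and 59.97 ± 52.1 CPM, and mast cell and basophil markers to 24.3 ± 24.3 and 53.3 ± 45.1 CPM. Erythroid markers summed to 1.11 ± 2.22 and 4.02 ± 8.05 CPM, platelet markers to 5.91 ± 8.57 and 0.0261 ± 0.0522 CPM, and adipocyte markers to 1.21 ± 2.32 and 0.0942 ± 0.163 CPM.

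The spread between libraries was large and the libraries of the genotypes differed in composition. The common dispersion was 2.36 over all tested genes, a biological coefficient of variation of 154%, against 0.161 over the 1211 most abundant ones. Across 2951 abundant genes, which are not independent replicates, the deviation of a library correlated with transcript GC content at 0.366, 0.0747, 0.180 and 0.107 in wild-type replicates 1 to 4 and at −0.0974, −0.212, −0.180 and −0.0435 in knockout (exact permutation p = 0.0286, adjusted 0.200 over 7 library measures, n = 4 each). The median log2 fold change of all tested genes was −0.12 with TMM and between −0.09 and −0.22 with the other scalings, and the directions given above for the 10 genes of smallest p and for the MHC class II genes held under each scaling. Among genes at an unadjusted p under 0.05, 48.8% were higher in knockout with TMM, 53.5% with RLE, 37.4% with upper-quartile scaling and 37.5% with library size only.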

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

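The tests of the GC trend against other divisions of the libraries and against gene detection, of the smallest p of any list, of CD8 and natural killer markers, and of B cell and macrophage markers were chosen after the result was seen. Of 104 groups of 4 libraries examined, 7 had a library far from the other 3, where chance gives about 1 in 20. Wild-type replicate 4 had 7957 detected genes (the others 9815 to 10140), 3167 CPM of Pkm (2484 to 2549) and 10500 CPM of glycolysis genes in sum (8385 to 8688). Wild-type replicate 1 had 25.4% of its counts in its 50 most abundant genes (21.8% to 22.3%) and 3421 CPM of monocyte, macrophage and dendritic cell markers (1520 to 1740). Knockout replicate 1 had 27.0 CPM of Tbx21 (0 to 0.111), and knockout replicate 4 had 14610 CPM of regulatory T cell genes (10200 to 10690).

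Counts of called genes were set against all 35 divisions of the 8 libraries into 4 and 4. edgeR called 0 genes at an adjusted p under 0.05 for the genotypes and up to 2 for another division; since any count reaches 0, all 35 of 35 gave as many by construction, which says nothing about chance. DESeq2 called 387 and limma voom 4. At an unadjusted p under 0.05, edgeR gave 326 genes, the most in any division (1 of 35, the others 36 to 272). This is the best rank that 35 divisions allow, unadjusted for the other results ranked on them, so it does not by itself exclude chance. The 272 came from wild-type replicates 1 to 3 and knockout replicate 3 against the rest. Evenly spread p-values would give 424, which no division reached. DESeq2 called 387 genes for the genotypes. It was run on 17 divisions, the genotypes and others drawn at random, and 2 gave as many, the genotypes included. The highest other count was 578. That division set the 4 libraries with the most detected genes (wild-type replicates 1 to 3 and knockout replicate 3) against the rest. No test related the calls to gene detection. For lists past camera, 7 of 35 divisions gave at least the 1 of the genotypes (highest other 3), so chance is not excluded for the count.

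The fold change fell as transcript GC content rose, with a Spearman correlation of −0.358 across genes for the genotypes, farther from 0 than in any other division (1 of 35; next −0.302). It did not rest on one library, since leaving out each in turn left it at −0.288 or lower, and it did not follow from transcript length and abundance, since the partial correlation was −0.316. Whether poor gene detection accounts for it stays open: in 6 of 12 pairs of libraries of one genotype the library with fewer genes had the lower GC correlation. A difference in library preparation that followed genotype may be a cause and cannot be told apart from the knockout itself, since the labels give no batch.

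For the genotypes, the Th1 and cytotoxic list had its smallest camera p of any division (0.000173, 1 of 35, next smallest 0.00539). No other list had a smaller p in another division either (1 of 35, next smallest 0.00037). That 0.00037 came from wild-type replicates 1 to 3 and knockout replicate 3, the 4 libraries with the most detected genes, against the rest. A rank of 1 of 35 is the best possible and was not adjusted for the other results ranked on these divisions. The ranks put the genotypes first but do not by themselves exclude chance. The GC trend is argued against as the whole cause: with the GC offset the median moved from −1.10 (interquartile range 1.30) to −1.25 (1.04), and the adjusted p was 0.000945 at the preset correlation used for the divisions too (without the offset, adjusted p = 0.572 with an estimated correlation). A general loss of scarce transcripts in knockout would lower random lists matched on expression as well, among which the list median stood at percentile 0. The genes of those lists were drawn independently, so the percentile takes no account of correlation between members. T cell identity stood at the percentile 0.12 among its own matched lists. The percentile argues against such a loss only in so far as members vary independently. More CD8 T or natural killer cells in wild type stay open: 12 of their markers outside the list differed by −0.168 wild-type SDs (229 ± 78.2 and 216 ± 109 CPM), with a spread too wide to exclude a drop, though the sort for CD4 would remove most such cells, Cd8a was at 0 in 3 of 4 wild-type libraries, and 4 of the 6 tested members of their list had higher estimates (median 1.35, percentile 99.52). A lower Th1 program in the knockout cells remains open as a hypothesis beside it.

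The MHC class II transcripts summed to 1624 ± 872 CPM in wild type and 7797 ± 4072 CPM in knockout, a sum of transcripts singled out because they were higher. The GC trend would lower and not raise them, and their median log2 fold change was 2.47 with the GC offset. B cell and macrophage markers did not rise alike. The larger rise of their marker sums was 0.176% of the rise of the 4 transcripts, with Lyz2 at 6.47 CPM and Cd79a at 2.25 CPM in knockout. This argues against these cells as the source only in so far as their markers were not lost from the knockout libraries. Only 11 of 14 B cell markers were among the symbols. Dendritic cell markers were judged by another test and not by such a share. Dendritic cells, some of which carry CD4 and could pass the gate, may be a source. For 24 of their markers not looked at before, the sums were 394 ± 190 and 762 ± 353 CPM. That is the direction needed, but the exact permutation p was 0.171 (n = 4 each). By library the sum was 1015, 1116, 444 and 475 CPM in knockout replicates 1 to 4. Knockout replicate 4, the highest in the MHC class II sum though not in H2-Ab1 or H2-Eb1, thus lay below wild-type replicate 4 (671 CPM). The question stays open, also because the most abundant of these markers, Cd83 (206 ± 146 and 432 ± 317 CPM), is made by activated T cells too. The markers did not move together. Ppt1 (77.5 ± 45.4 and 170 ± 110 CPM) and Rab7b (0.22 ± 0.28 and 71.3 ± 106 CPM) were higher in knockout. Ckb (64.8 ± 25.2 and 26.4 ± 26.4 CPM) and Clec10a (14.5 ± 10.7 and 5.67 ± 11.3 CPM) were lower. Sirpa and Itgax, seen in wild-type replicate 1 alone, were at 0 in every knockout library. Which kind of dendritic cell could be present was not tested.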

How the results depend on the processing

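The alternatives with a minimum mean CPM of 50, with the GC offset, with both, and without the libraries of fewest genes were chosen after seeing the data. edgeR called 0 genes at an adjusted p under 0.05 in every edgeR setting tried, including the replicate block (0, with 327 at an unadjusted p under 0.05) and each library left out (0 each time, with 289 to 904 at an unadjusted p under 0.05; 904 without knockout replicate 3). DESeq2 called 387 genes and limma voom 4 (Ltb, Zgpat and Pccb lower, Skil higher). Voom with quality weights called 4 (Ltb and Aldoa lower, Skil and Ets1 higher). The cause of the difference between tools was not tested. Of the DESeq2 calls, 92.5% were at 0 in at least 1 library, as were 4703 of the 8489 genes tested in edgeR. In the simulation at fitted dispersions, DESeq2 made 144 false calls and edgeR 0. The adjusted p of Slc7a5 was 0.365 in edgeR, 0.437 to 0.542 with a library left out, 0.953 with the replicate block and 0.0183 with DESeq2; the stricter filter removed the gene.

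Lists past camera numbered 1, against 4 with a mean CPM of 50 or more, 2 with that filter and the GC offset, 0 with an estimated correlation, 2 with fry's mixed test (Th1 and cytotoxic, and apoptosis and p53) and 0 to 2 with a library left out (2 without wild-type replicate 1 or knockout replicate 1, 0 without wild-type replicate 4 or knockout replicate 3). The adjusted p of the Th1 and cytotoxic list was 0.572 with an estimated correlation and 0.00241 to 0.142 with a library left out; it was under 0.05 in 18 of 21 alternatives (0.000179 to 0.572). At a mean CPM of 50 or more, the adjusted p was 0.00883 for glycolysis, 0.0127 for T cell identity and 0.00738 for the monocyte, macrophage and dendritic cell list, each past the threshold with fewer genes tested (3472). Of 561 list results under alternatives, 552 stayed on their side of the threshold. A list that passed in neither fit counts as such whatever its direction, and 61 of these results flipped direction against other genes.

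Of 414 results of the 19 named genes under alternatives, 399 kept direction and call and 9 gained a call. Reversed were Gata3 (log2 fold change 0.26 with quality weights, 0.26 without knockout replicates 2 and 4, 0.30 without the 3 libraries of fewest genes, and −0.22 to 0.10 with a library left out) and Il17a (0.11 with quality weights); the cause was not tested. The libraries gave no clear sign that the replicate numbers pair them, and the labels do not settle it. Same-numbered libraries correlated at −0.022, 0.018, 0.021 and 0.053 after removal of group means. The 0.053 was the highest between any wild-type and knockout library. Of 8 libraries, 3 correlated best with their own number, and the block changed no call. Of 8489 tested genes, 4703 were at 0 in at least 1 library although no library held under 18837650 counts; the cause of these zeros was not tested.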

Other observations

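6 further gene groups were defined by symbol after the data were seen, and all tests in this paragraph were chosen then. Splicing regulators of the SR and Clk families had higher estimates for 12 of 16 tested members, a median log2 fold change of 0.53, and a summed CPM of 3926 ± 538 in wild type and 6893 ± 1497 in knockout. This group was drawn up after its member Clk1 had been seen among the 5 higher genes with the smallest p, and the group of classical MHC class II genes from the 4 transcripts already seen to be higher. A test of either on these libraries would restate that, so none is given. Of the others, cytosolic ribosomal protein genes (75 tested) had a camera adjusted p of 0.0830 in the upward direction although their median log2 fold change was −0.09. It was 0.0117 with the GC offset, and adjusted p = 0.618 with an estimated correlation. The camera adjusted p of proteasome subunits was 0.133, of histone genes 0.133 and of genes of the actin cytoskeleton 0.924 (0.118, 0.960 and 0.960 with the GC offset).

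Of 3 transcripts that dendritic cells make, all noticed in these data before the list of further dendritic cell markers was written, Cst3 and Naaa were lowest in knockout replicate 3 and highest in replicate 4 among knockout libraries, as the MHC class II sum was (8632, 9885, 1840 and 10830 CPM in knockout replicates 1 to 4). Plbd1 was at or near 0 in replicates 3 and 4, at 147, 308, 0 and 0.10 CPM in knockout and 9.97 ± 11.8 CPM in wild type. Cst3 was at 505, 861, 225 and 1164 CPM in knockout replicates 1 to 4 and 255 ± 91.4 CPM in wild type, and Naaa at 91.8, 103, 17.3 and 261 CPM and 4.25 ± 4.49 CPM. No explanation was tested with them.

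Loss of detection was lopsided between genotypes. 58 genes had counts in all 4 wild-type libraries and in 0 knockout libraries, and 1 gene the reverse, which needs detection in knockout replicate 4 with its 5221 genes. 176 of the 1904 genes seen in exactly 3 wild-type libraries were at 0 in every knockout library, Slc7a5 among them, and 24 genes seen in exactly 3 knockout libraries were at 0 in every wild-type library. Actb took 7.40%, 4.78%, 5.57% and 3.09% of the counts in wild-type replicates 1 to 4 and 3.70%, 13.8%, 8.47% and 5.75% in knockout.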
